A study of Homo sapiens with 24 samples.

How the data were processed

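Total RNA from Caco-2 and T84 cells was measured on 24 Affymetrix-type oligonucleotide arrays of 22283 probe sets, 1 array per sample. Per the labels, the cells were cultured on Transwell filters for 14 days and stimulated for 4 h or left unstimulated, in 8 groups of 3 arrays. Every column was matched to a sample by its identifier. The deposited values were used as log2 values. The labels do not state the unit: the base follows from the range, since the highest values read as natural logarithms would exceed what a 16-bit scanner can record. The method that summarised probes into probe sets, the background correction and the normalization are not given in the sources used here. Array medians differed by at most 0.163, under the limit of 0.25 set for rescaling, so the values were not normalized further. Raw scanner files were not used here. No genome build is given, so no coordinates are reported.

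Of the probe sets, 68 were array controls and left out of the tests, 19065 named 1 gene, 1043 named several genes and 2107 were not listed in the probe table used. Probe sets with several genes or none were not counted as genes. Gene identifiers were matched to current symbols for 19053 probe sets, and 0 symbols needed an update. The 11963 named genes included 4310 with several probe sets, and the probe set with the highest mean over all arrays stood for the gene. A gene was tested when at least 3 arrays lay above the 40th percentile of all values (5.17), which left 9395 genes. Signal over this floor is what limits the dim genes.

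Linear models with 8 group means were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 16 residual degrees of freedom). Moderated t tests compared each stimulus with the control of its line, the stimuli with each other, the unstimulated lines, and the response of T84 with that of Caco-2. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes were called at an adjusted p under 0.05. All p-values in the text come from limma unless another test is named.

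The 20 gene lists, of 498 entries of which 442 were named on the array and 368 tested, covered chemokines, cytokines and growth factors, NF-kB components and feedback genes, receptors of the TNF and lymphotoxin family, the Toll-like receptor pathway, immediate early genes, the interferon response, antigen presentation, adhesion, tight junctions, apoptosis, mucosal defence, enterocyte function, the cell cycle, endoplasmic reticulum stress and heat shock, cholesterol synthesis, and markers of goblet and enteroendocrine cells, fibroblasts, leukocytes and endothelial cells. Each list was tested with camera at a preset correlation between genes of 0.01, again with a correlation estimated from the list, and with fry, and adjusted over the 20 lists. Members were also adjusted over the list alone. That was done separately for each list and each comparison, with no adjustment over the 20 lists or over the comparisons. A gene that passed over the list alone is therefore a weaker result than one called over all genes.

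The comparisons, the lists, the settings and the rule for named genes were chosen before the data were examined. The rule named, per comparison with a control, the 10 largest rises and the 10 largest falls among the genes called whose 3 stimulated arrays lay outside the range of the controls. It added up to 4 called members of each list, or the 2 with the largest change where none was called, and 9 genes in every case: CXCL8, CCL20, NFKBIA, TNFAIP3, BIRC3, ICAM1, TLR5, TNFRSF1A and LTBR. Of these, 8 were tested. BIRC3 was not named in the probe table, so any probe set that measures it would have no gene listed. For differences between lines or stimuli it named the 5 largest in each direction, and for the unstimulated lines the 10 largest. Other genes, among them those past the test adjusted over the list alone, were named after their values were seen.

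The alternatives were quantile normalization over all arrays or within each line, no filter, a filter at the 60th percentile, every probe set tested, the replicate number as a block, each line or each pair of groups fitted alone, a trended and robust variance, array weights, a fold change of at least 1.5, and leaving out each array in turn. Other pseudocounts had no meaning for log2 values. The standard deviation of each array as a covariate, leaving out the 8 arrays of narrow spread, and leaving out each array in turn for the gene lists, were added after the data were seen. The models were tested on simulated data with 50 genes changed at each size: at a change of 1.00, 76% were recovered for TNFa in Caco-2, 84% for TNFa in T84 and 40% for the difference between them, with 8, 9 and 6 false calls. The simulated genes were independent and had the same spread in every group. These shares and false calls therefore need not hold for the real arrays of either line. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.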

Results

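Gene expression was measured in 2 human colon carcinoma cell lines that form polarised epithelial layers. Caco-2 cells take on features of absorptive enterocytes in long culture, and T84 cells resemble crypt cells that secrete chloride. Both were grown on permeable filters for 14 days and then left alone or stimulated for 4 h with flagellin, the bacterial protein sensed by Toll-like receptor TLR5, with lymphotoxin beta (LTb), or with tumour necrosis factor alpha (TNFa). Each of the 8 groups held 3 samples, and each sample was read on its own array, 24 in all. Doses, and the form in which lymphotoxin beta was given, are not stated in the sources used here. Nothing says that the 3 samples of a group came from separate cultures, so all p-values measure the spread between these samples, which may be technical. With 3 arrays per group, the number of arrays limits the precision. Of 11963 named genes, 9395 were bright enough to be tested. Changes are differences of group means on the log2 scale, given with their standard error (SE), and genes were called at an adjusted p under 0.05 from limma. Each SE uses a spread pooled over the 8 groups of both lines. It is too wide for groups that vary less and too narrow for groups that vary more.

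The cell line separated the arrays most: the first principal component held 53.5% of the variance and the second 23.6%. No arrays held identical values, and the highest correlation between any pair was 0.995. Array medians lay between 5.38 and 5.54, but the spread of the values within an array differed, with standard deviations from 1.15 (T84 control 1) to 1.45 (T84 control 3). The 3 T84 control arrays therefore differed from each other more than the arrays of other groups did, with a mean spread of 1.30 ± 0.15 (SD, n = 3) against 1.42 ± 0.02 for the T84 LTb arrays. T84 control 1 stood apart from all other arrays: 16 genes lay over 1 above and 118 over 1 below all other T84 arrays, and its distance to its nearest array was 0.496, against 0.275 or less on the others. Its mean over the NF-kB list was 5.75, against 6.26 and 6.29 on the other T84 controls. The 3' to 5' difference of the ACTB control probe sets, a measure of RNA integrity, was 0.53 ± 0.57 on the T84 control arrays, 0.32 ± 0.56 with flagellin, 0.31 ± 0.24 with TNFa and 0.01 ± 0.32 with LTb (log2, SD, n = 3). In Caco-2 it lay between -0.21 ± 0.06 with flagellin and 0.07 ± 0.05 on the controls.

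**Figure D1:**
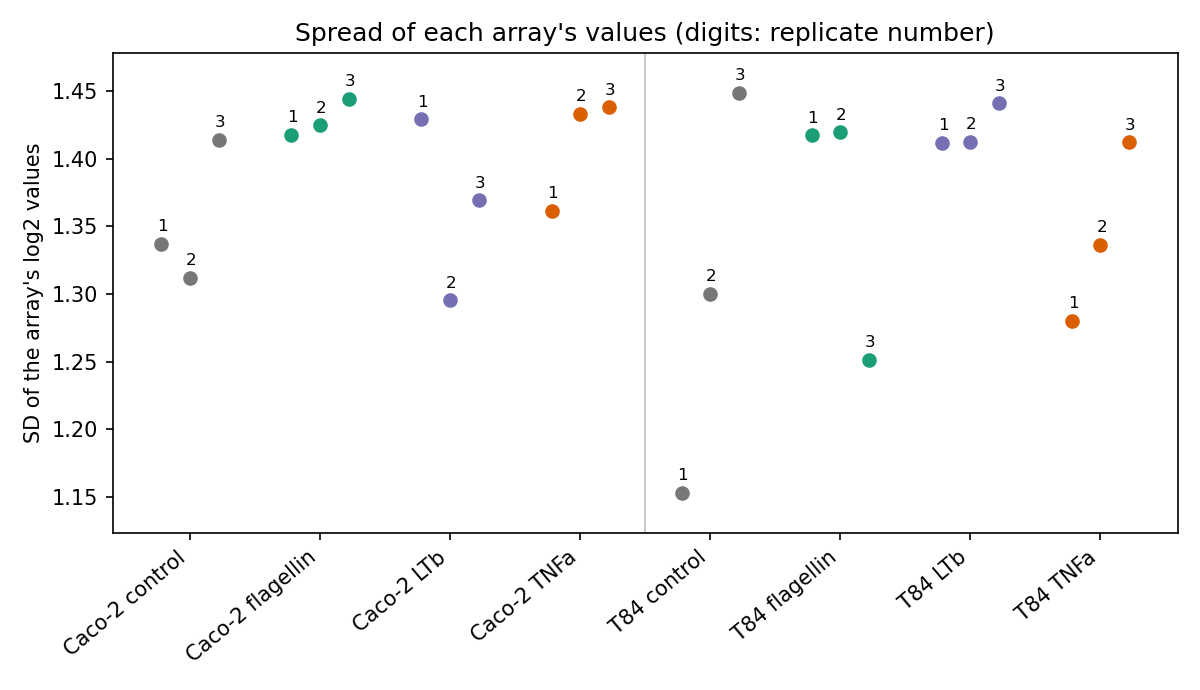
Standard deviation of the log2 values of each array (vertical axis, log2 units) for the 8 groups (horizontal axis); each point is an array and the digit is its replicate number. The T84 controls span 1.15 to 1.45, and the T84 LTb arrays 1.41 to 1.44.

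The first comparison was of Caco-2 cells with TNFa against unstimulated Caco-2 cells. Genes that switch NF-kB signalling off were among those that rose most. TNFAIP3, which encodes the ubiquitin-editing inhibitor A20, rose by 1.87 ± 0.20 (SE, n = 3; adjusted p = 3.53e-05), from 6.87 ± 0.11 to 8.74 ± 0.18 (SD). NFKBIA, the inhibitor IkB alpha, rose by 1.90 ± 0.31 (adjusted p = 0.00718), and TNIP1, a partner of A20, by 1.45 ± 0.28 (adjusted p = 0.0374). The heparan sulfate proteoglycan SDC4 rose by 1.53 ± 0.19, the interferon-inducible chemokine CXCL10 by 1.08 ± 0.17, the collagenase MMP1 by 1.30 ± 0.23 and the tetraspanin-like surface protein TM4SF1 by 1.22 ± 0.23. These were the 7 genes called, and each was higher on 3 of 3 stimulated arrays than on any control array; chance separates 3 arrays from 3 others, in either direction, for 10% of genes. CCL20, the chemokine that draws dendritic cells and T cells through CCR6, differed by 1.88 ± 0.37 and did not pass (adjusted p = 0.0523). IL32, a proinflammatory cytokine, differed by 1.09 ± 0.25 (adjusted p = 0.160) and IER3, an early response gene, by 1.00 ± 0.21 (adjusted p = 0.0742).

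Among the gene lists, 3 of the 21 measured NF-kB components and feedback genes rose with TNFa in Caco-2, or 7 adjusted over the list alone, which added NFKBIE (0.59 ± 0.16), RELB (0.80 ± 0.25), NFKB2 (0.70 ± 0.19) and IKBKE (0.43 ± 0.16). The list ranked above the other genes (median 0.19, camera adjusted p = 1.17e-08; adjusted p = 0.0820 with an estimated correlation). Receptors of the TNF family were called (median 0.13, adjusted p = 0.00439; adjusted p = 0.0660 with an estimated correlation): none of 10 passed over all genes, and 2 passed adjusted over the list alone, the death receptor TNFRSF10B (0.77 ± 0.20) and osteoprotegerin, TNFRSF11B (0.78 ± 0.23). Immediate early genes were called too (median 0.19, adjusted p = 2.33e-07; adjusted p = 0.179 with an estimated correlation), with IER3 passing adjusted over the list alone. Antigen presentation genes had a median of 0.17 (adjusted p = 0.000560; adjusted p = 0.283 with an estimated correlation), and 0 of 22 passed in limma on either adjustment. Adjusted over the list alone, 2 of 11 chemokines passed (CXCL10 and CCL20), 1 of 19 cytokines (IL32), 1 of 20 apoptosis genes (BIK, 0.62 ± 0.16) and 2 of 25 mucosal defence genes (the elastase inhibitor PI3, 0.89 ± 0.22, and complement C3, 0.73 ± 0.20). Of the chemokines the median (-0.02) and the mean (0.27) differed in sign. The bioB control value was 6.57 ± 0.11 on the TNFa arrays against 7.25 ± 0.16 on the controls (log2, SD, n = 3), with no overlap. Cholesterol synthesis genes ranked higher (median 0.16) and leukocyte markers lower (median -0.14), each at adjusted p = 0.00439 and adjusted p = 0.382 with an estimated correlation, on arrays whose mean spread was 0.06 wider than that of the controls; with array spread in the model both calls ended (adjusted p = 0.239 and 0.337), and the medians of the NF-kB list and of the receptors became 0.07 and 0.05. Calls also ended without 1 array: that of the receptors without control 3 (adjusted p = 0.0523), of cholesterol synthesis without TNFa array 2 (0.0645) and of leukocyte markers without control 2 (0.0877). The NF-kB list stayed called in each refit, with medians of 0.08 without control 1, 0.12 without TNFa array 2 and 0.32 without TNFa array 1. The median of antigen presentation was 0.27 without TNFa array 1 and 0.11 without array 3. The count of 7 genes fell to 3 without Caco-2 control 1 or control 2 and to 2 without TNFa array 2 or array 3; TNFAIP3 and SDC4 passed in every such refit. With quantile normalization the count was 11, with each line fitted alone 29 and with array spread in the model 21.

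In T84 cells TNFa acted on many of the same feedback genes. CCL20 rose by 4.07 ± 0.37 (SE, n = 3; adjusted p = 7.44e-07), a 16.8-fold difference, from 5.37 ± 0.64 to 9.44 ± 0.28 (SD). TNFAIP3 rose by 2.65 ± 0.20 (adjusted p = 4.00e-08), NFKBIA by 2.53 ± 0.31, SDC4 by 2.01 ± 0.19, IL32 by 1.64 ± 0.25 and TNIP1 by 1.56 ± 0.28. Both chains of the interferon gamma receptor were among the genes called, IFNGR1 at 1.51 ± 0.28 and IFNGR2 at 1.10 ± 0.17. TM4SF1 rose by 1.43 ± 0.23, the NF-kB subunit RELB by 1.22 ± 0.25 (adjusted p = 0.0360), the matrix protease matrilysin, MMP7, by 1.15 ± 0.23, IER3 by 1.03 ± 0.21, the inhibitor NFKBIE by 0.95 ± 0.16 and the decoy interleukin-1 receptor IL1R2 by 0.87 ± 0.14. Of these 14 genes called 12 differed at least 2-fold, and all were higher on 3 of 3 stimulated arrays than on any control. CXCL8 (interleukin-8), a neutrophil chemokine, differed by 1.19 ± 0.43 and did not pass over all genes (adjusted p = 0.859), though it did adjusted over the list alone (0.0389). Its values spread widely with TNFa, 7.01 ± 0.66 against 5.82 ± 0.09 in the controls. The SE is pooled over all 8 groups, and the widest was Caco-2 LTb (6.33 ± 1.57, SD), so the test of CXCL8 is weak in every comparison. In T84 it read 6.40 ± 0.13 with LTb and 6.03 ± 0.10 with flagellin. In Caco-2 it read 5.14 ± 0.12 on the controls, 5.56 ± 0.03 with flagellin and 5.73 ± 0.09 with TNFa.

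With all arrays kept, the NF-kB list moved further than any other list tested in T84 cells with TNFa: 5 of 21 members rose, or 12 adjusted over the list alone, with a median of 0.52. It ranked above the other genes at camera adjusted p = 1.55e-17, and also with an estimated correlation (adjusted p = 0.0105). Of the 36 list calls over the 6 comparisons with a control, this was the 1 call that held with an estimated correlation. Chemokines had a median of 0.30 (adjusted p = 7.49e-05; adjusted p = 0.163 with an estimated correlation), and CCL20, CXCL10 (0.57 ± 0.17) and CXCL8 passed adjusted over the list alone. Cytokines and growth factors had a median of 0.20 (adjusted p = 0.000210; adjusted p = 0.151 with an estimated correlation), with IL32, the stem cell cytokine LIF (0.61 ± 0.14) and LTB (0.78 ± 0.21) passing adjusted over the list alone. Interferon response genes were called (median 0.13, adjusted p = 0.00815; adjusted p = 0.272 with an estimated correlation) with 1 of 31 passing adjusted over the list alone, the antiviral enzyme OAS3 (0.75 ± 0.17). Immediate early genes had 4 of 30 passing adjusted over the list alone (IER3, CEBPD, DUSP5 and JUNB) and a median of 0.21 (adjusted p = 0.00143; adjusted p = 0.380 with an estimated correlation). The antigen presentation, apoptosis and cholesterol synthesis lists were called as well, and lost their calls with an estimated correlation (adjusted p = 0.380, 0.446 and 0.649). With array spread in the model the apoptosis and cholesterol synthesis calls ended (adjusted p = 0.139 and 0.151), and the median of the immediate early genes became 0.08. TAP1, the peptide transporter, and the apoptosis genes BIK and CFLAR passed adjusted over the list alone. Leukocyte, endothelial and fibroblast markers had medians between 0.03 and 0.06 and were not called. The endothelial mean (-0.02) differed in sign from its median, and the test placed cell cycle genes lower (adjusted p = 0.724) though their median was 0.07. The NF-kB call stayed in every refit without 1 array, but its median was 0.24 without T84 control 1. The chemokine medians over such refits lay between 0.10 and 0.35. Without control 3 the chemokine (median 0.10, adjusted p = 0.242), cytokine (0.449) and interferon (0.306) calls ended, and without control 2 (adjusted p = 0.0802) or TNFa array 3 (0.106) that of the immediate early genes. The interferon call ended without TNFa array 3 as well (0.0788), and the medians of the interferon and immediate early lists were 0.06 and 0.07 without control 1. The highest medians of these lists over the refits without 1 array were 0.26 and 0.34. The antigen presentation, apoptosis and cholesterol synthesis calls ended without control 1 (adjusted p = 0.0647, 0.155 and 0.335), control 2 (0.110, 0.323 and 0.524) or TNFa array 3 (0.0788, 0.254 and 0.372). The number of genes called was 7 without T84 control 1, 37 without control 3, 9 without TNFa array 2 and 6 without TNFa array 3; CCL20, TNFAIP3, NFKBIA, SDC4 and IL32 passed in each. Without the arrays of narrow spread, which leaves 1 control and 1 TNFa array, it was 4, as it was with each line fitted alone; with quantile normalization it was 31 and with array spread in the model 43.

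With LTb 34 genes changed in T84 cells. CCL20 rose by 3.10 ± 0.37 (SE, n = 3; adjusted p = 0.000114), from 5.37 ± 0.64 to 8.47 ± 0.18 (SD), or 8.57-fold. TNFAIP3 rose by 2.13 ± 0.20 (adjusted p = 3.10e-06), NFKBIA by 2.36 ± 0.31, IL32 by 1.79 ± 0.25, TNIP1 by 1.77 ± 0.28, SDC4 by 1.36 ± 0.19 and NFKBIE by 1.15 ± 0.16. TAP1 rose by 1.36 ± 0.26 (adjusted p = 0.0125), IFNGR1 by 1.41 ± 0.28 (adjusted p = 0.0182), MMP7 by 1.27 ± 0.23 and the secreted trefoil peptide TFF1 by 1.04 ± 0.23 (adjusted p = 0.0356). HSP90B1, a chaperone of the endoplasmic reticulum, rose by 1.99 ± 0.39 (adjusted p = 0.0144), but its other probe set differed by 0.18 ± 0.25, while a probe set listed for both HSP90B1 and MIR3652 differed by 1.85 ± 0.37 (adjusted p = 0.0386 among the probe sets outside the gene tests). All 34 genes were higher with LTb, on 3 of 3 arrays above every control, and 22 differed at least 2-fold. At an unadjusted p under 0.05 there were 1994 genes, 1424 of them higher, where 469.8 would be expected by chance if genes were independent. With TNFa in T84 cells there were 416. The SE is pooled over both lines, and the T84 controls differed in spread (array SD 1.15 to 1.45). The excess with LTb therefore cannot be read as the size of a response.

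Several gene lists moved with LTb in T84 cells. Of the 21 NF-kB genes 4 rose, or 11 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 2.38e-06; adjusted p = 0.405 with an estimated correlation). Antigen presentation genes had 1 of 22 called (TAP1) and 10 adjusted over the list alone, among them the immunoproteasome subunits PSMB8 (1.06 ± 0.30), PSMB9 (0.46 ± 0.19) and PSMB10 (1.17 ± 0.32), TAPBP (0.78 ± 0.25) and B2M (0.48 ± 0.15). Their median was 0.37 (adjusted p = 0.0141; adjusted p = 0.419 with an estimated correlation). The apoptosis list (median 0.31, adjusted p = 0.00514) and the adhesion list (median 0.37, adjusted p = 0.00895) each had 4 members passing adjusted over the list alone, among them CYCS, BID, CD59 and LAMB3; both had adjusted p = 0.419 with an estimated correlation. Interferon response genes went both ways, 5 higher and 2 lower (MX2, -0.66 ± 0.19, and IFI6, -0.44 ± 0.15) adjusted over the list alone, and the list was not called (adjusted p = 0.954). Immediate early genes had 4 higher and NR4A1 lower (-0.53 ± 0.16) adjusted over the list alone, and the list was not called. CA2 (0.86 ± 0.21) and CFTR (0.62 ± 0.18), of the enterocyte list, passed adjusted over the list alone. FCGBP, a goblet cell mucus protein, was lower (-0.49 ± 0.14) on the same adjustment. In camera the goblet and enteroendocrine list was not called (adjusted p = 0.253), nor was mucosal defence (adjusted p = 0.217). The enterocyte, chemokine, cytokine and Toll-like receptor lists were not called (adjusted p from 0.709 to 0.954). For chemokines and cytokines the medians (-0.07 and -0.03) and the means (0.28 and 0.15) differed in sign, as did median and mean of the mucosal defence list (-0.11 and 0.01). Tight junction genes had a median of 0.39 and receptors of the TNF family 0.29, with no member past the test on either adjustment and no call in camera (each adjusted p = 0.215). The fry test, which does not compare with other genes, called the receptors with LTb (adjusted p = 0.0123) and with TNFa (0.0249; camera 0.149) in T84 cells. Without T84 control 1 the medians of the adhesion and cholesterol synthesis lists were 0.18 and 0.37, and those of the NF-kB list and of endoplasmic reticulum stress 0.29 and 0.28. All 4 stayed called. The highest medians over the refits without 1 array were 0.62, 0.75, 0.58 and 0.66 in that order, and 0.47 for apoptosis (lowest 0.21).

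Lists of highly expressed housekeeping functions were higher on the same arrays, and markers of other cell types lower. Cholesterol synthesis genes had a median of 0.64 (camera adjusted p = 0.000872; adjusted p = 0.419 with an estimated correlation), and 9 of 14 passed adjusted over the list alone, among them SQLE (0.74 ± 0.22) and DHCR7 (0.66 ± 0.17). Endoplasmic reticulum stress and heat shock genes had a median of 0.44 (adjusted p = 0.000127; adjusted p = 0.456 with an estimated correlation), and 7 of 22 passed adjusted over the list alone, among them HSP90B1, HERPUD1 (1.09 ± 0.37) and DNAJB9 (1.01 ± 0.32). Cell cycle genes had a median of 0.37 with 30 of 31 above 0 (adjusted p = 0.00395; adjusted p = 0.554 with an estimated correlation), and none passed on either adjustment. Endothelial (median -0.30, adjusted p = 0.0141), leukocyte (median -0.16, adjusted p = 0.0395) and fibroblast markers (median -0.22, adjusted p = 0.0395) ranked below the other genes; with an estimated correlation these had adjusted p = 0.419, adjusted p = 0.462 and adjusted p = 0.419. Of these markers, CLDN5 (-0.77 ± 0.22) passed adjusted over the list alone. The 3' to 5' difference of GAPDH was 0.16 ± 0.05 with LTb against 0.44 ± 0.21 in the controls (log2, SD, n = 3), with no overlap, and that of ACTB 0.01 ± 0.32 against 0.53 ± 0.57. The LTb arrays had a mean spread 0.12 wider than the controls, the brightest 20% of all genes had a median change of 0.37 and the dimmest 20% -0.09. With array spread in the model, the medians became 0.19 for cholesterol synthesis, 0.08 for endoplasmic reticulum stress, -0.04 for the cell cycle and -0.01 for leukocyte markers, while that of the NF-kB list was 0.38. The calls of the adhesion list (median 0.12, adjusted p = 0.109) and of the endothelial, fibroblast and leukocyte markers (adjusted p = 0.105, 0.647 and 0.809) ended, as did those of the cell cycle and endoplasmic reticulum stress lists. Antigen presentation (median 0.10) and apoptosis (median 0.11) stayed called. Leaving out T84 control 1 ended the cell cycle call (median 0.11, adjusted p = 0.0762). Those of the fibroblast and leukocyte markers ended without control 1 (adjusted p = 0.0793 and 0.108), control 2 (0.135 and 0.257), LTb array 2 (each 0.0631) or LTb array 3 (0.131 and 0.162). Over the refits without 1 array the medians ran from -0.46 to -0.25 for endothelial, -0.33 to -0.05 for leukocyte and -0.32 to -0.13 for fibroblast markers.

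The number of genes called with LTb in T84 cells moved with single arrays of both groups. It was 9 without T84 control 1, 32 without control 2 (22 of them shared with the 34) and 2792 without control 3, and 10, 18 and 11 without LTb array 1, 2 or 3. CCL20, NFKBIA, TNFAIP3, IL32, TNIP1, SDC4 and NFKBIE passed in each of these refits, and HSP90B1, IFNGR1, TAP1, MMP7 and TFF1 did not pass without control 1. Without the arrays of narrow spread, which leaves 1 T84 control, 2 genes passed, NFKBIA and TNFAIP3. With each line fitted alone the count was 6, and with every probe set tested it was 65. Set beside the 14 genes of TNFa, the order of the counts turned with quantile normalization (29 with LTb and 31 with TNFa), with array spread in the model (27 and 43), without the arrays of narrow spread (2 and 4) and with the 2 groups fitted alone (3 and 4).

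**Figure D2:**
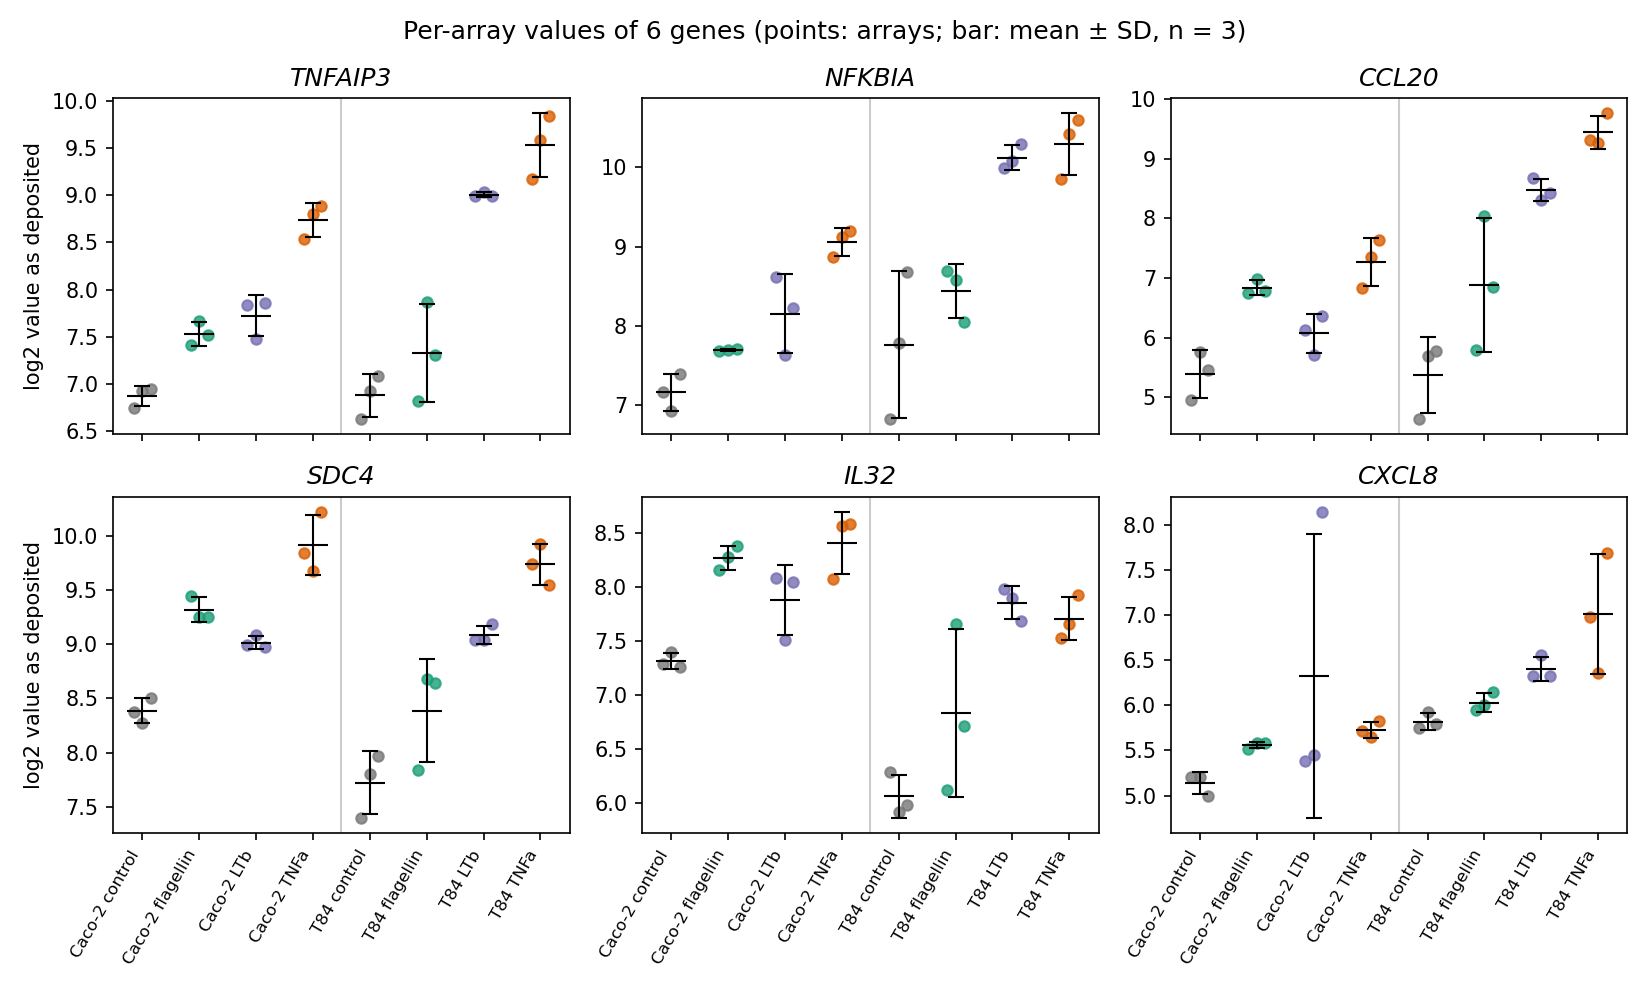
Per-array log2 values (vertical axes) of TNFAIP3, NFKBIA, CCL20, SDC4, IL32 and CXCL8 in the 8 groups (horizontal axis), points for arrays and bars for the mean ± SD (n = 3). CCL20 reached 9.44 ± 0.28 with TNFa and 8.47 ± 0.18 with LTb in T84 cells, and in Caco-2 cells CXCL8 stood at 8.14 on LTb array 3 alone.

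In Caco-2 cells no gene passed with LTb in limma, and 41 had an unadjusted p under 0.05, where 469.8 would be expected by chance. The SE is pooled over both lines, so this count does not measure chance for Caco-2 alone. NFKBIA differed by 1.00 ± 0.31 and TNFAIP3 by 0.85 ± 0.20 (SE, n = 3), each with an adjusted p of 1.00. Adjusted over the list alone, these were 2 of 21 NF-kB genes past the test (0.0413 and 0.00726). The NF-kB list had a median of 0.09 (camera adjusted p = 0.00528) and the chemokine list 0.08 (adjusted p = 0.0325), and both had adjusted p = 0.844 with an estimated correlation; with array spread in the model the chemokine call ended (adjusted p = 0.0559). The NF-kB call ended without control 1 (median 0.014, adjusted p = 0.0743) or control 3 (0.026, adjusted p = 0.0759), and its median was 0.15 without LTb array 2 and 0.038 without LTb array 3. The chemokine call ended without control 3 (median -0.038, adjusted p = 0.664), LTb array 2 (0.378) or LTb array 3 (0.153). On the LTb arrays the 3' to 5' difference of ACTB was -0.09 ± 0.06 against 0.07 ± 0.05 on the controls (log2, SD, n = 3), with no overlap. CCL20 differed by 0.68 ± 0.37 and IL32 by 0.56 ± 0.25. CXCL8 differed by 1.19 ± 0.43, but 8.14 on LTb array 3 stood against 5.38 and 5.45 on the other LTb arrays, and its other probe set differed by 0.02 ± 0.20. Counts by the other tools were 0 with each line fitted alone, 0 with a trended and robust variance, 13 with array weights, a fit that warned of non-convergence, and 1 with array spread in the model.

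With flagellin, 2 genes rose in Caco-2 cells. MMP1 rose by 1.42 ± 0.23 (SE, n = 3), from 6.44 ± 0.31 to 7.86 ± 0.11 (SD), and PI3 by 1.39 ± 0.22, from 6.05 ± 0.12 to 7.44 ± 0.13. Both had an adjusted p of 0.0104 and were higher on 3 of 3 arrays than on any control; the other PI3 probe set differed by 0.72 ± 0.13. CCL20 differed by 1.44 ± 0.37, KRT20, a keratin of mature enterocytes, by 1.03 ± 0.25, IL32 by 0.96 ± 0.25, TNIP1 by 0.84 ± 0.28, TNFAIP3 by 0.66 ± 0.20 and NFKBIA by 0.53 ± 0.31, all with an adjusted p of 0.824. Adjusted over the list alone, 2 of 11 chemokines (CCL20 and CXCL10), 1 of 19 cytokines (IL32), 2 of 18 adhesion genes (CEACAM1, 0.63 ± 0.18, and CEACAM5, 0.58 ± 0.15), 1 of 20 apoptosis genes (BIK), 2 of 25 mucosal defence genes (PI3 and C3) and 1 of 32 enterocyte genes (KRT20) passed, all higher. No gene of the NF-kB list passed on either adjustment, and the list was not called (median 0.04, camera adjusted p = 0.610). The adhesion list (median 0.20, adjusted p = 0.00345) and the apoptosis list (median 0.12, adjusted p = 0.0355) were called, each with adjusted p = 0.540 with an estimated correlation. Cholesterol synthesis (median 0.36, adjusted p = 0.000345; adjusted p = 0.540 with an estimated correlation), cell cycle (median 0.17, adjusted p = 0.00890; adjusted p = 0.701 with an estimated correlation) and endoplasmic reticulum stress genes (median 0.20, adjusted p = 0.0252; adjusted p = 0.701 with an estimated correlation) ranked higher, and leukocyte markers lower (median -0.16, adjusted p = 0.00890; adjusted p = 0.540 with an estimated correlation). Beside these, the flagellin arrays had a mean spread 0.07 wider than the controls, and the brightest and dimmest 20% of all genes had medians of 0.20 and -0.08. The 3' to 5' difference of ACTB was -0.21 ± 0.06 against 0.07 ± 0.05 on the controls, and the bioB control value 6.68 ± 0.08 against 7.25 ± 0.16 (log2, SD, n = 3), both with no overlap. With array spread in the model the adhesion (median 0.13) and cholesterol synthesis (median 0.12) calls stayed, and those of apoptosis, the cell cycle, endoplasmic reticulum stress and leukocyte markers ended (adjusted p = 0.208, 0.223, 0.600 and 0.523). Without 1 array the adhesion and cholesterol synthesis calls stayed, with an adhesion median of 0.34 without control 3. The apoptosis call ended without control 1 (adjusted p = 0.0893), control 3 (0.0709) or flagellin array 1 (0.0808), and that of leukocyte markers without control 2 (0.112). The cell cycle and endoplasmic reticulum stress calls ended without control 1 (0.0893 and 0.0929) or control 2 (each 0.126), and without flagellin array 2 (0.0614) and array 3 (0.0699) in turn. Their medians over the refits without 1 array ran from 0.07 to 0.30 and from 0.14 to 0.28. Leaving out any array but Caco-2 control 3 ended both gene calls, and leaving that array out kept MMP1 alone; without the arrays of narrow spread there were 0 genes in limma, with each line fitted alone 5 and with array spread in the model 4. In all, 370 genes had an unadjusted p under 0.05.

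No gene passed with flagellin in T84 cells in limma (lowest adjusted p = 0.764), and 520 had an unadjusted p under 0.05. Of the genes named in every case, CCL20 differed by 1.52 ± 0.37 (SE, n = 3), NFKBIA by 0.68 ± 0.31 and TNFAIP3 by 0.45 ± 0.20. The rule also named list members for their large change in these data. Among them were LCN2, the iron-binding defence protein lipocalin, at 0.96 ± 0.28, IL32 at 0.77 ± 0.25 and CA2 at 0.71 ± 0.21. The flagellin arrays disagreed with each other: CCL20 read 5.79, 8.03 and 6.84 on arrays 1, 2 and 3, against 4.64 to 5.78 on the controls, and was the 1 gene of the chemokine list past the test adjusted over the list alone (0.00539). The NF-kB list ranked above the other genes (median 0.20, camera adjusted p = 0.0111), as did cholesterol synthesis (median 0.37, adjusted p = 0.0111) and endoplasmic reticulum stress genes (median 0.19, adjusted p = 0.0345), while endothelial markers ranked below (median -0.24, adjusted p = 0.0486). With an estimated correlation each of these had adjusted p = 0.821. The NF-kB call ended without T84 control 1 (median 0.10, adjusted p = 0.282), control 3 (0.105), flagellin array 2 (median 0.18) or flagellin array 3 (0.136), and the median was 0.31 without control 2 and 0.30 without control 3 or flagellin array 1. The cholesterol synthesis and endoplasmic reticulum stress calls ended without control 1 (medians 0.12 and 0.06; adjusted p = 0.208 and 0.282), control 2 (0.413 and 0.756), flagellin array 1 (0.112 and 0.634) or array 2 (medians 0.24 and 0.10). The highest medians over the refits without 1 array were 0.54 for cholesterol synthesis and 0.42 for endoplasmic reticulum stress. The endothelial call ended without any 1 of the 6 arrays (adjusted p from 0.0574 to 0.413). The flagellin arrays had a mean spread 0.06 wider than the controls, and with array spread in the model the NF-kB call alone of these stayed (median 0.14); the others had adjusted p = 0.0533, 0.522 and 0.243. Other tools called 0 genes with each line fitted alone, with a trended and robust variance or with array spread in the model, and 5224 with array weights. Leaving out T84 control 3 gave 361 genes, and leaving out flagellin array 1 gave 1, CCL20.

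The lines were then compared for each stimulus by the difference of their changes, T84 minus Caco-2. No gene passed this test in limma for TNFa, LTb or flagellin, and 197, 589 and 289 genes had an unadjusted p under 0.05. Among the 1915 probe sets with several genes or none, 1 passed for LTb (2.21 ± 0.35, adjusted p = 0.00386), with no gene listed. For TNFa 1 passed (-1.92 ± 0.34, adjusted p = 0.0251), listed for both UBD and GABBR1. For LTb, CCL20 differed by 2.42 ± 0.53 (SE, 3 arrays per group), the growth factor feedback gene SOCS2 by 0.95 ± 0.21, TNFAIP3 by 1.28 ± 0.29 and the desmosome gene DSC2 by 1.07 ± 0.24, all with an adjusted p of 0.492. Adjusted over the list alone, CCL20, IL32 and 3 of 21 NF-kB genes (NFKBIA, TNFAIP3 and NFKBIE) passed. For TNFa, IL1R2 differed by 0.94 ± 0.20 (adjusted p = 0.917) and CCL20 by 2.20 ± 0.53, the latter passing adjusted over the list alone (0.00423). For flagellin, PI3 differed by -1.41 ± 0.31 and MMP1 by -1.18 ± 0.32 (each adjusted p = 0.999), and of the mucosal defence list PI3, DMBT1 (-0.83 ± 0.25) and LCN2 (1.22 ± 0.40) passed adjusted over the list alone. Of 20 lists, 7 differed between the lines with LTb and 1 with TNFa on the preset correlation of camera, and none with an estimated correlation (lowest adjusted p = 0.532 and 0.651). The NF-kB list differed with LTb (median 0.47) in every refit without 1 array, at 0.23 without T84 control 1. Array weights called 904 genes for LTb, 535 for TNFa and 1228 for flagellin; each of the other tools called 0, and 1 gene passed for LTb without T84 control 3.

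Of the 14 genes called with TNFa in T84 cells and the 7 in Caco-2, 5 were called in both, TNFAIP3, NFKBIA, SDC4, TNIP1 and TM4SF1, where 0.0104 would be expected for independent lists. Of the 14, 13 went the same way in Caco-2, and their median change was 1.47 in T84 and 1.05 in Caco-2. Of the 7, all 7 went the same way in T84, with medians of 1.45 in Caco-2 and 1.56 in T84. Choosing genes by their change in a line favours that line, so these medians do not compare the lines. With each line fitted alone the order of the counts turned, with 4 genes in T84 and 29 in Caco-2. Of the 34 genes called with LTb in T84, 26 went the same way in Caco-2, with medians of 1.04 and 0.17, and 6 had an unadjusted p under 0.05 there. These genes too were chosen by their change in T84. Over all tested genes, 54.8% had the same sign in both lines with TNFa, 56.6% with LTb and 63.8% with flagellin; genes are not independent replicates.

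**Figure D3:**
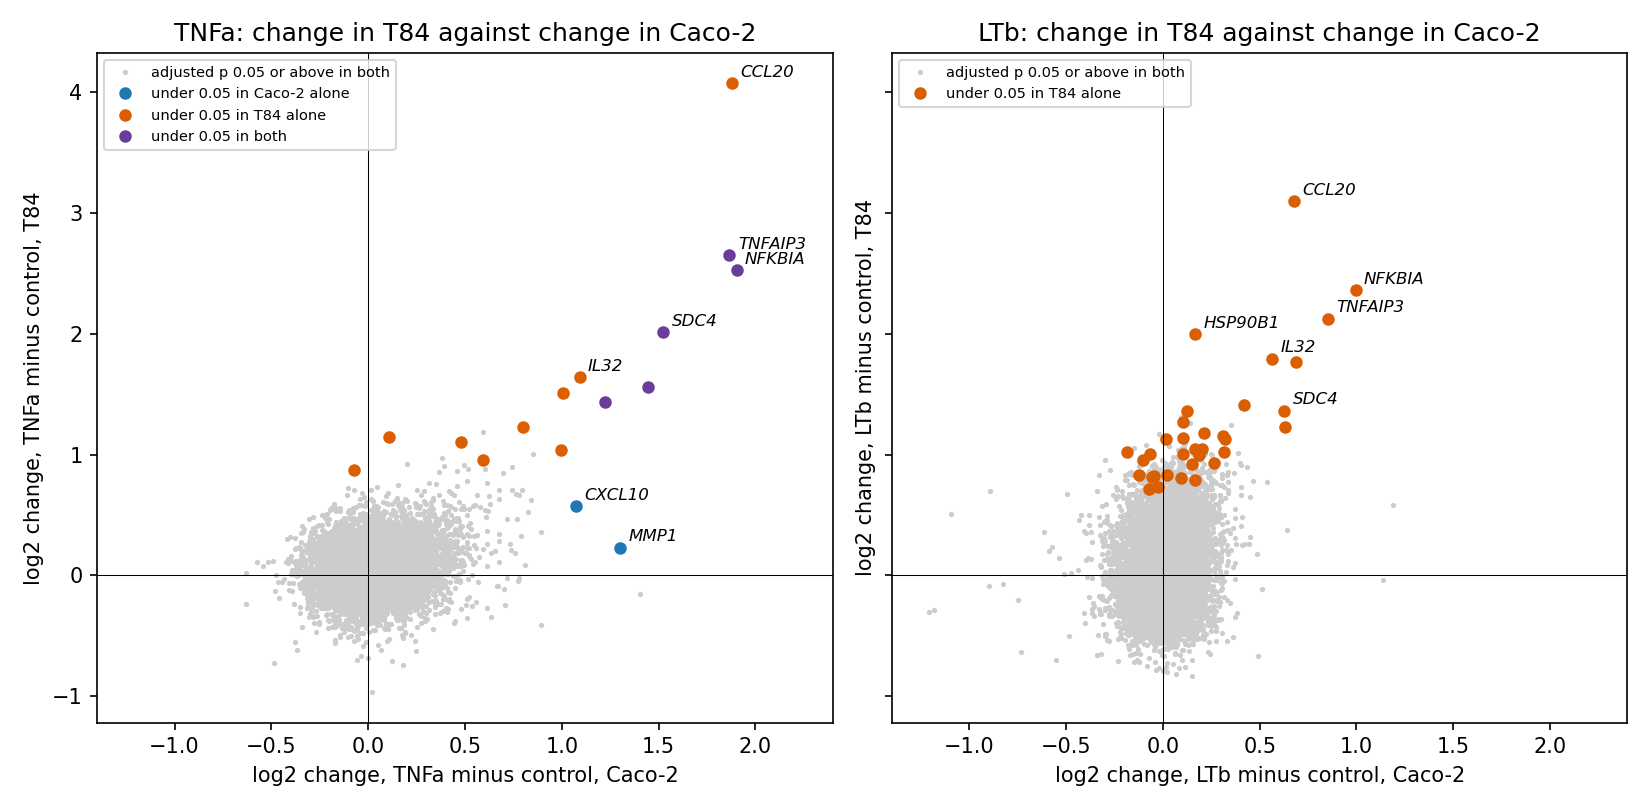
Log2 change of each tested gene in T84 (vertical axes) against its change in Caco-2 (horizontal axes) for TNFa (left) and LTb (right), with coloured points for genes at an adjusted p under 0.05. With TNFa 5 genes passed in both lines, and with LTb 34 passed in T84 and 0 in Caco-2.

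Stimuli were also set against each other within a line. In T84 cells, TNFa gave higher values than flagellin for 4 genes: CCL20 by 2.56 ± 0.37 (SE, n = 3; adjusted p = 0.00181), TNFAIP3 by 2.20 ± 0.20, NFKBIA by 1.85 ± 0.31 and SDC4 (2.54-fold; adjusted p = 0.00152). Flagellin gave a lower value than LTb for 1 gene, TNFAIP3 (-1.68 ± 0.20; adjusted p = 0.000239), and 3 genes passed without flagellin array 2. With each line fitted alone these counts were 1 and 0 (479 genes at an unadjusted p under 0.05 in limma for flagellin against LTb), with the 2 groups alone 2 and 2, without the arrays of narrow spread 2 and 2, and with array spread in the model 10 and 4. TNFAIP3 was also the 1 gene higher with TNFa than with flagellin in Caco-2 (1.21 ± 0.20; adjusted p = 0.0441), and it did not pass when any array of those groups was left out. No gene differed between TNFa and LTb in T84 cells in limma, with 972 genes at an unadjusted p under 0.05, nor in Caco-2 (146 genes), nor between flagellin and LTb in Caco-2 (183 genes). For those 3 comparisons array weights called 1261, 40 and 10 genes, each line fitted alone 0, 2 and 1, a fit of the 2 groups alone 4, 0 and 1, and array spread in the model 0, 3 and 2.

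LTb and TNFa shared 11 of their 34 and 14 called genes in T84 cells, among them CCL20, NFKBIA, TNFAIP3, SDC4, IL32, TNIP1 and MMP7. Independent lists would share 0.0507 genes, and 50 simulations of unchanged groups against shared controls gave a mean of 0. No gene was changed in these simulations, so a shared count near 0 was set in advance for any pair. It cannot show how much overlap the shared controls bring among called genes. The simulated genes were also independent, with the same spread in every group. The covariance of the changes was 0.0389 against 0.0212 in the simulations, the correlation over genes 0.582 against 0.502, and the share of genes with the same sign 68.1% against 66.7%. Both comparisons used the same 3 control arrays, too few to split, and part of the excess may come from them. Flagellin and TNFa shared MMP1 in Caco-2 (0.00149 expected, 0.02 in the simulations), with a covariance of 0.0324 against 0.0212. On all arrays of both groups the bioB control value lay below every Caco-2 control (6.68 ± 0.08 and 6.57 ± 0.11 against 7.25 ± 0.16, log2, SD). Of the pairs with no shared call, the covariance lay below the simulations in Caco-2 for LTb and TNFa (0.0114 against 0.0212) and for flagellin and LTb (0.0135 against 0.0211), and above them in T84 for flagellin and LTb (0.0569 against 0.0212) and for flagellin and TNFa (0.0272 against 0.0211). Unequal variation of the controls may give such a pattern, so no shared response is read from these covariances.

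The TNF receptor TNFRSF1A and the lymphotoxin beta receptor LTBR differed by 0.03 to 0.35 over the 6 comparisons, and none passed. TLR5 differed by -0.17 to 0.04, at group means of 5.11 to 5.34 near the filter value of 5.17. Array values went down to 3.03, so a fall could be recorded, but changes of such dim genes are hard to read. ICAM1, an adhesion molecule for leukocytes, differed by -0.39 to 0.08 at its brightest probe set, and did not pass, but its other probe sets disagreed with it for TNFa in Caco-2, at 0.81 ± 0.18 and 0.76 ± 0.15 against 0.07 ± 0.23. Where TNFAIP3 and IFNGR1 passed, their other probe set differed in the same direction, as did 2 of the 3 others of TM4SF1; the dimmest TM4SF1 probe set differed by 0.15 ± 0.17 with TNFa in Caco-2.

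Without stimulation the lines differed in 1546 genes, 549 higher and 997 lower in T84, and 457 of them at least 2-fold. The 10 genes furthest below Caco-2 in T84 were the apolipoproteins APOC3 (-5.25 ± 0.25), APOA2 (-5.03 ± 0.24), APOA1 (-5.03 ± 0.15) and APOB (-4.38 ± 0.18), transferrin TF (-5.09 ± 0.19), fetuin AHSG (-5.07 ± 0.27), SERPINA1 (-4.99 ± 0.19), angiotensinogen AGT (-4.52 ± 0.20), the fibrinogen chain FGG (-4.15 ± 0.25) and fibronectin FN1 (-5.16 ± 0.17). APOA1 read 5.68 ± 0.04 in T84 and 10.71 ± 0.23 in Caco-2 (SD, n = 3; adjusted p = 1.08e-16). The 10 furthest above were the protease inhibitor TIMP1 (4.34 ± 0.20), the lectin LGALS4 (4.15 ± 0.17), IFI27 (3.68 ± 0.28), CEMIP (3.55 ± 0.17), GPRC5A (3.46 ± 0.14), S100P (3.37 ± 0.19), PLBD1 (3.14 ± 0.23), the carcinoembryonic antigen CEACAM5 (3.05 ± 0.15), the hyaluronan receptor CD44 (2.90 ± 0.17) and ADIRF (2.88 ± 0.27). TIMP1 read 9.82 ± 0.24 in T84 and 5.47 ± 0.25 in Caco-2 (adjusted p = 6.46e-14). The division between higher and lower depended on the scaling, with 944 of 2105 genes higher after quantile normalization, 1285 of 2691 with array spread in the model, 2100 of 4506 with array weights and 919 of 1473 without the arrays of narrow spread. The count was 1038 without Caco-2 control 3 and 2183 without T84 control 3.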

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

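The explanations weighed here, the covariate for array spread, the fit without narrow arrays and the lists without single arrays were chosen only after the results were seen; the splits of the samples were planned.

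Some probe sets outside the gene tests, because the probe table gives them several genes or none, lay above the level of the controls. With TNFa in Caco-2 these were 2 probe sets, the first listed for both UBD and GABBR1 (2.26) and the second with no gene listed (1.29). In T84 they were 4: 2 that rose with both LTb and TNFa (2.28 and 1.73 for the first, 1.37 and 1.42 for the second), 1 with LTb, listed for both MIR3652 and HSP90B1 (1.85), and 1 with TNFa (1.14). The first and the last of these had no gene listed, and the second was listed for both MIR8085 and BCL3. The first of the T84 probe sets differed between the lines with LTb (2.21), and the first of the Caco-2 probe sets with TNFa (-1.92).

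Medians of 7 lists differed between the lines with LTb on the preset correlation: NF-kB components 0.47, adhesion 0.35, apoptosis 0.25, cell cycle 0.32, endoplasmic reticulum stress 0.37, cholesterol synthesis 0.51 and endothelial markers -0.28. With TNFa the NF-kB list differed by 0.24, and its call ended without T84 control 1 (0.06, adjusted p = 0.119), Caco-2 TNFa 1 (0.0648) or T84 TNFa 3 (0.0562). With LTb the NF-kB call stayed in every refit without 1 array. Without T84 control 2 each of the other 6 calls ended (adjusted p from 0.0680 to 0.127). The adhesion and apoptosis calls also ended without T84 LTb 3 (0.172 and 0.0618), and the adhesion, cell cycle and endothelial calls without T84 control 1 (0.0951, 0.103 and 0.0851), Caco-2 control 3 (0.0809, 0.142 and 0.159) or Caco-2 LTb 2 (0.0559, 0.0922 and 0.0686). The adhesion call ended without Caco-2 control 1 (0.0549) or Caco-2 LTb 3 (0.0764) as well, and the endothelial call without Caco-2 LTb 3 (0.0666) or T84 LTb 1 (0.0859). Without T84 control 1 the medians with LTb were 0.23 for NF-kB, 0.15 for adhesion, 0.14 for apoptosis, 0.099 for the cell cycle, 0.21 for endoplasmic reticulum stress 0.22 for cholesterol synthesis and -0.33 for endothelial markers. None of these passed with an estimated correlation (lowest adjusted p = 0.532 and 0.651).

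Bright housekeeping lists were called higher, and markers of other cell types lower, in several comparisons. With array spread in the model 18 of the 36 list calls were kept in all, and 0 of the 11 calls of the cell cycle, endoplasmic reticulum stress, leukocyte, endothelial and fibroblast lists, and unequal spread of the arrays may account for these. Of the 5 calls of the cholesterol synthesis list, 2 were left, which keeps both explanations open. The spread itself goes with the T84 groups, 1.42 ± 0.02 with LTb against 1.30 ± 0.15 in the controls, so a response of these genes to the stimuli cannot be told apart from it and was not tested.

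T84 flagellin array 1 lay near the controls, with CCL20 at 5.79 and TNFAIP3 at 6.82 against 6.84 or more and 7.30 or more on the other flagellin arrays, though NFKBIA, at 8.69, was the highest of the 3 flagellin arrays (8.58 and 8.05; T84 control 3 read 8.68). This array and T84 control 3 were each the nearest array of the other, with ACTB 3' to 5' differences of 0.97 and 0.91. A swap with a T84 control may explain it and stays open: 0 control arrays reached the lower of the other flagellin arrays for CCL20 and TNFAIP3, but these 2 genes define the pattern; a narrow spread of the array is argued against by its standard deviation of 1.42. An unstimulated or barely stimulated sample stays open too: of 7 genes called with TNFa in Caco-2, 2 lay above all T84 controls on this array, 6 on array 2 and 3 on array 3, so arrays 1 and 3 both stayed under the limit of 4.04. An earlier count over 37 genes chosen against the same controls gave 16, 34 and 18, all over its limit of 14.5, and the 7 genes were taken after that count was seen.

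CXCL8 read 8.14 on Caco-2 LTb array 3 and at most 5.82 on the other Caco-2 arrays. This array stands apart as a whole: 7 genes lay over 1 above and 12 over 1 below all other Caco-2 arrays (0 and 0 on each of those), and its 28S (6.03) and bioB (5.54) control values were the lowest of all 24 arrays. T84 cells in the sample are argued against, since the highest T84 value was 7.69. The genes called with TNFa showed no stronger response, with a median -0.12 from the higher of the other LTb arrays. No gene was called with LTb in Caco-2, so those genes need not report the LTb response. The NF-kB list mean was 6.45 on this array, against 6.44 and 6.27 on LTb arrays 1 and 2. A stronger LTb response therefore stays open. A defect at 1 probe set may explain the CXCL8 value and stays open too. The second CXCL8 probe set was 0.30 above the mean of the other Caco-2 arrays, at a level under the 5.17 floor. It lay above each of them (4.55 against at most 4.41).

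For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. The splits with at least as many genes, the real count and the highest other count were, in Caco-2, 1, 2 and 0 for flagellin, 10, 0 and 0 for LTb and 1, 7 and 0 for TNFa, and in T84 10, 0 and 4104 for flagellin, 2, 34 and 52 for LTb and 2, 14 and 1526 for TNFa. Between stimuli in Caco-2 they were 1, 1 and 0 for TNFa against flagellin, and 10, 0 and 0 for each of TNFa against LTb and flagellin against LTb. In T84 they were 2, 4 and 395, then 10, 0 and 0, then 1, 1 and 0 in that order, and between the unstimulated lines 1, 1546 and 0. For lists called they were 2, 6 and 6, 5, 2 and 7, and 4, 6 and 9 for flagellin, LTb and TNFa in Caco-2, and 3, 4 and 6, 1, 10 and 7, and 1, 8 and 6 in T84.

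For the difference between lines, the real count was 0 genes (limma; 289, 589 and 197 at an unadjusted p under 0.05 for flagellin, LTb and TNFa), so 100 of 100 splits reach it whatever the data; the same holds wherever the real count above is 0, and these say nothing about chance. The highest others were 4034, 807 and 1005. Splits that call many genes point to a structure of the samples. The split with 4104 genes set T84 flagellin 1, flagellin 2 and control 3, the arrays of wider spread, against flagellin 3, control 1 and control 2, those of narrower spread, and the split with 1526 set TNFa 1, control 1 and control 2 against the rest.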

How the results depend on the processing

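The counts below follow the order flagellin, LTb and TNFa against control in Caco-2 (main 2, 0, 7) and T84 (0, 34, 14), the line differences (0, 0, 0), TNFa against flagellin, TNFa against LTb and flagellin against LTb in Caco-2 (1, 0, 0) and T84 (4, 0, 1), and the unstimulated lines (1546). Of 278 gene results named, none reversed; quantile normalization kept 273 on the same side of the threshold, no filter 278, trended variance 275, the spread covariate 269 and the fit without narrow arrays 255. Leaving out T84 control 3 kept 90 of 139, with 49 newly past it. Signal over the floor limits the dim genes. Pseudocounts were not run. Unless said, the cause was not tested. The covariate and the fit without narrow arrays were added after the data were seen; the latter leaves 1 control per line and 1 T84 TNFa array, assumed to vary like the other groups.

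By setting the counts were: quantile over all arrays, Caco-2 TNFa 11, T84 TNFa 31, Caco-2 pairs 2 and 1, T84 flagellin against LTb 2; within lines 13, 30, 2, 1 and 2. Every probe set gave T84 LTb 65. No filter and trended variance gave 0 for Caco-2 TNFa against flagellin. Each line alone gave Caco-2 5, 0, 29, T84 0, 6, 4 and pairs 2, 2, 1 and 1, 0, 0. The 2 groups alone gave 13, 0, 13, 0, 3, 4, pairs 9, 0, 1 and 2, 4, 2, and 399. Array weights, whose fit warned of non-convergence, gave 4431, 13, 3788, 5224, 4800, 535, differences 1228, 904, 535, pairs 42, 40, 10 and 1750, 1261, 124, and 4506. The spread covariate gave 4, 1, 21, 0, 27, 43, pairs 5, 3, 2 and 10, 0, 4, and 2691. Without narrow arrays they were 0, 0, 5, 0, 2, 4, pairs 3, 0, 0 and 2, 0, 2, and 1473. List calls were 36, and 26 with quantile normalization, 35 with the block, 25 with the covariate, 23 without narrow arrays, 1 with an estimated correlation and 12 with fry, and 26 (T84 control 1) to 42 (Caco-2 TNFa 1) without 1 array, a setting added after the data were seen.

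The direction of the camera test turned, and its call ended, for 4 list results, with medians under the covariate and without narrow arrays of -0.078 and -0.091 (cell cycle, Caco-2 flagellin), 0.0026 and -0.0063 (endoplasmic reticulum stress, Caco-2 flagellin), -0.040 and -0.13 (cell cycle, T84 LTb) and -0.010 and 0.0043 (leukocyte markers, T84 LTb). Under the covariate the second and the last median kept their sign.

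Leaving out 1 array gave 0 to 1, 0 to 0 and 2 to 7 in Caco-2, 0 to 361, 9 to 2792 and 6 to 37 in T84, differences 0 to 0, 0 to 1 and 0 to 0, Caco-2 pairs 0 to 0, T84 pairs 3 to 5, 0 to 0 and 1 to 3, and 1038 to 2183; the highest T84 values against control were without control 3. The replicate block gave 2, 0, 8, 0, 28, 14 and 1541; 15 of 36 same-number pairs correlated over 0.1 (-0.80 to 0.63) and 7 of 24 arrays matched their own number best.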

Other observations

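The genes in this paragraph were chosen after their values were seen. Among the other genes called with LTb in T84 cells (SE, n = 3, limma), no group was tested. The common cytokine receptor chain IL2RG rose by 0.83 ± 0.15, the ubiquitin ligase TRIM31 by 1.18 ± 0.22, the signalling adaptor STAP2 by 1.02 ± 0.17, the feedback gene SOCS2 by 0.83 ± 0.15 and NAMPT, an enzyme of NAD synthesis that is also secreted, by 0.93 ± 0.17. The integrin ITGAV rose by 1.13 ± 0.24, the desmosomal cadherin DSC2 by 1.01 ± 0.17, the serine protease TMPRSS2 by 0.83 ± 0.16, STEAP1 by 0.92 ± 0.18 and SDCBP, a binding partner of syndecans such as SDC4, by 1.00 ± 0.20. The autophagy receptor SQSTM1 rose by 0.80 ± 0.17 and the transcription factor NFE2L3 by 1.14 ± 0.22. Each was higher on 3 of 3 LTb arrays than on any control, as were all 34 genes called. Without T84 control 1 the count with LTb was 9. CCL20, NFKBIA, TNFAIP3, IL32, TNIP1, SDC4 and NFKBIE were among those left. Most genes of this paragraph therefore lost their call without that array.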
